A study of Drosophila melanogaster with 12 samples.

How the data were processed

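Total RNA of Drosophila melanogaster larvae was measured on 12 one-channel (Cy3) Agilent expression arrays, 3 in each of 4 groups. Per the labels, larvae of a w1118 control or of a REPTOR knockout ate food with 200 µM rapamycin, or food with ethanol alone, for 6 h. They were taken 48 h before wandering and are labelled female, and 0.5 µg of RNA went into each labelling. The series describes the arrays of a group as biological replicates.

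The deposited scanner files hold spot intensity values per the file headers, extracted with Agilent Feature Extraction 10.7 per the submitters' processing notes. The column used was the processed signal, a background-corrected intensity. The deposited value table holds a second kind of intensity, which the authors made by a step that neither the labels nor the headers record. Set against the scanner values, it followed the median spot signal after quantile normalisation between arrays, on a linear scale and with no background subtraction. Its column medians ran from 144 to 157. It served as an alternative.

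Each array carried 43602 spots other than controls. Between 72.5% and 82.7% of them were well above background, and 0 were saturated. The number of arrays limits the precision of every comparison.

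The log2 processed signal of each array was taken relative to that array's 75th percentile. Control spots and spots with an outlier mark were left out, and spots of 1 probe were averaged. The 32162 probes point to 25857 target sequences. Only 491 probes matched exactly 1 gene symbol in the reference table, through an accession or a synonym. Another 3 matched several and 31668 matched none. A class-prefixed name that holds only a CR or CG number was treated like the bare number. The unit tested was therefore the gene, or the target sequence where no symbol was found, 25842 in all. Each was represented by its probe with the highest mean over the 12 arrays. A unit was tested if that probe was well above background on all 3 arrays of at least 1 group, which left 18765. Of these, 275 had a symbol, bare numbers included. Below, a gene with a symbol is one whose symbol is not a bare number.

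No probe matched REPTOR, REPTOR-BP, Thor, unk, InR or crc, so these genes were not analysed here and the genotype labels were not checked through the targeted gene.

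Groups were compared with limma 3.58.1 in R 4.3.3, in a single model with 4 groups and 8 residual degrees of freedom. The adjusted p-values are those of limma with Benjamini-Hochberg adjustment, two-sided, with a threshold of 0.05. The contrasts were rapamycin against ethanol in each genotype, the difference of these effects, knockout against control on each food, and the mean rapamycin effect over genotypes. The mean effect selected responding targets without favouring a genotype, and on these the difference was adjusted over the list alone. The median level of these targets per array gave a score. Its difference of rapamycin effects was tested by an exact two-sided permutation of the genotype labels within each food (400 arrangements, smallest p 0.005). The targets were not selected again in each arrangement, so this p is exact for the fixed score and not for the selection. The permutation also assumes no genotype effect on either food. An exact test of 3 arrays against 3 cannot go below 0.1. Errors of fold changes are standard errors from the model, and those of levels are SDs over 3 arrays.

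Named genes followed a rule fixed before the data were examined. Per contrast it took the 10 highest and 10 lowest fold changes with a gene symbol, and the 2 highest and 2 lowest of all. For the knockout contrast on rapamycin food and for rapamycin in knockout larvae it took 5 and 5, with 1 and 1 of all. Apart from the difference of effects, the arrays of both groups also had to be free of overlap. A target not well above background in a whole group is given as a bound. This is the brighter group's mean over the dim group's mean of, per array, the higher of the dim probe's own signal and the lowest signal well above background. It concerns the group means alone and leaves out the spread between arrays.

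Of 32 gene lists fixed before the data were examined, 10 had a tested member and only the cytosolic ribosomal proteins had at least 4. Lists were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation as the alternative. Because so few names matched, 10 sets were added after the data had been seen, from classes of symbols and from the cDNA libraries whose clones name the targets. With 1 fixed list large enough to test, its adjusted p equals the unadjusted p. Fixed lists and added sets were adjusted separately, a choice made after the first set tests were seen.

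Alternatives were other scalings, the deposited value table, other filters, the mean of all probes, slide or replicate number as a block, within-slide fits, another variance model, array weights, stricter thresholds and leaving out each array. Background correction by normexp was planned on mean signals, which are not among the columns used here, and was run on median signals instead. It was run once with all spots kept. After that result was seen, it was run again without 4 spots of 1 array whose local background was over 100 times the array's median. Leaving out 3 arrays with a raised roX2 signal and using roX2 as a covariate were also chosen after the data were seen.

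The arrays lay on 3 slides, and scan order followed slide. Slide 1 held the control ethanol arrays and control rapamycin array 1. Slide 2 held control rapamycin arrays 2 and 3 and knockout ethanol arrays 1 and 2. Slide 3 held knockout ethanol array 3 and the knockout rapamycin arrays. No slide held both genotypes on the same food, so a slide block links the genotypes only indirectly. With that block the rapamycin effect of control larvae comes from slide 1 alone, and that of knockout larvae from slide 3 alone.

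The steps were tested on simulated data with the real mean and spread of each target. Noise was drawn independently for each target and array, without deviations shared by many targets of an array. Only 50 targets were changed per size, whereas 43.1% of real targets passed for rapamycin in control larvae. The shares below therefore test the steps and do not give the recovery in these data. For rapamycin in control larvae, over 18741 targets, 40% of simulated log2 changes of 0.5 were recovered, 76% of changes of 1 and 92% of changes of 2. For the difference of effects the shares were 18%, 56% and 84%. Unchanged targets were called 8 and 6 times among 18541. Tables were prepared in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and figures drawn with matplotlib 3.10.9.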

Results

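Transcript levels were measured in whole-larva RNA after 6 h of feeding on rapamycin, an inhibitor of the TORC1 kinase complex, in control larvae and in larvae lacking REPTOR, a bZIP transcription factor that acts downstream of TORC1. Each of the 4 groups (control or knockout, ethanol or rapamycin food) had 3 arrays, and 18765 genes or target sequences were tested. Between 72.5% and 82.7% of the spots of an array were well above background. Levels below are log2 signals relative to the array's 75th percentile. Most targets carry only a sequence identifier here, so named genes are a small part of each response.

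The first comparison asked what rapamycin did in control larvae. Nepl4, which encodes a neprilysin-like peptidase, rose by 3.16 ± 0.12 (log2, SE, n = 3 arrays per group, adjusted p = 2.56e-07), the most of any gene with a symbol. Wdr59 and mio, which encode subunits of the GATOR2 complex upstream of TORC1, rose by 1.71 ± 0.11 (adjusted p = 3.14e-06) and 1.51 ± 0.06 (adjusted p = 2.63e-07). Hsl, encoding hormone-sensitive lipase, rose by 0.94 ± 0.08 (adjusted p = 1.87e-05) and f-cup by 1.58 ± 0.07 (adjusted p = 4.47e-07). The snoRNA host genes Uhg5 and Uhg2 fell by 1.83 ± 0.13 and 1.07 ± 0.12 on the log2 scale, and TrpRS, a tryptophanyl-tRNA synthetase, fell by 1.33 ± 0.11 (adjusted p = 1.13e-05).

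The other named genes that rose in control larvae were snRNA:U11, an RNA of the minor spliceosome (1.40 ± 0.27, well above background on 2 of the 3 ethanol arrays), atos (1.38 ± 0.11), RpL30 (0.87 ± 0.16), mxt, encoding an eIF4E-binding translation factor (0.81 ± 0.08), and Gen, encoding a DNA endonuclease (0.76 ± 0.17). With normexp and all spots kept, the direction turned for snRNA:U11 (-0.44) and mxt (-0.05), and atos had 0.34 (adjusted p = 0.503). Those that fell were shop (-1.06 ± 0.16), the mitochondrial aspartate-glutamate carrier gene aralar1 (-0.97 ± 0.14), the cuticle protein gene Cpr49Ag (-0.96 ± 0.13), the cyclophilin gene Cyp1 (-0.85 ± 0.12) and 3 mitochondrial ribosomal protein genes given next. Among targets without a symbol, FBtr0087746 (6.73 ± 1.14) and FBtr0085307 (4.44 ± 0.62) rose most, and FBtr0087117 (-4.02 ± 0.51) and FBtr0078507 (-3.82 ± 0.29) fell most.

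By the lists fixed beforehand, all 3 measured mitochondrial ribosomal protein genes fell in control larvae, mRpS16 (-0.87 ± 0.16), mRpL52 (-0.85 ± 0.14) and mRpL14 (-0.84 ± 0.16). The 4 measured cytosolic ribosomal protein genes went different ways: RpL30 rose, RpS14b rose by 0.23 ± 0.07 (adjusted p = 0.0169, but 0.00 under median centring), RpS7 fell by 0.77 ± 0.11 (adjusted p = 0.000337) and RpS29 (-0.55 ± 0.25, adjusted p = 0.101) did not pass. As a set the 4 did not pass (camera adjusted p = 0.999). Their levels in control larvae on ethanol lay far apart, at 3.84 for RpS14b, 0.21 for RpL30, -3.73 for RpS7 and -4.36 for RpS29. Of the TORC1 pathway list mio and Wdr59 rose, and Wdr24, the other GATOR2 subunit measured, did not pass (0.12 ± 0.11, adjusted p = 0.401). Of the remaining lists with a measured member, Atg10 (autophagy) rose by 0.50 ± 0.06 and CtsB (cathepsin B) by 0.50 ± 0.14, whereas Vha13 (a vacuolar ATPase subunit) fell by 0.65 ± 0.09, Ald1 (aldolase, glycolysis) by 0.83 ± 0.12 and Cpr60D (cuticle) by 0.48 ± 0.10. ATPCL, the fatty acid synthesis member, had 0.12 ± 0.18 (adjusted p = 0.632), and the cuticle gene Acp65Aa had -0.63 ± 0.32 (adjusted p = 0.149). List members outside the rule for named genes were named after their values were seen. Adjusted over the list alone, every list gave the same counts.

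In total, 8082 targets passed the threshold in control larvae, 3984 higher and 4098 lower, and 1590 of these changed at least 2-fold. In 7967 of the 8082 the arrays of both groups did not overlap, which held for 57.0% of all tested targets against 10% by chance. With slide as a block 4683 targets passed, 4470 of them among the 8082 and in the same direction, and within slide 1, which holds a single control rapamycin array, 2799 passed on a spread taken from the ethanol arrays alone. The share of higher calls depended on the scaling: centring arrays on the median in place of the 75th percentile gave a median of all targets of -0.18 in place of 0.05 and left 3848 calls, 21.9% of them higher against 49.3%.

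**Figure D1:**
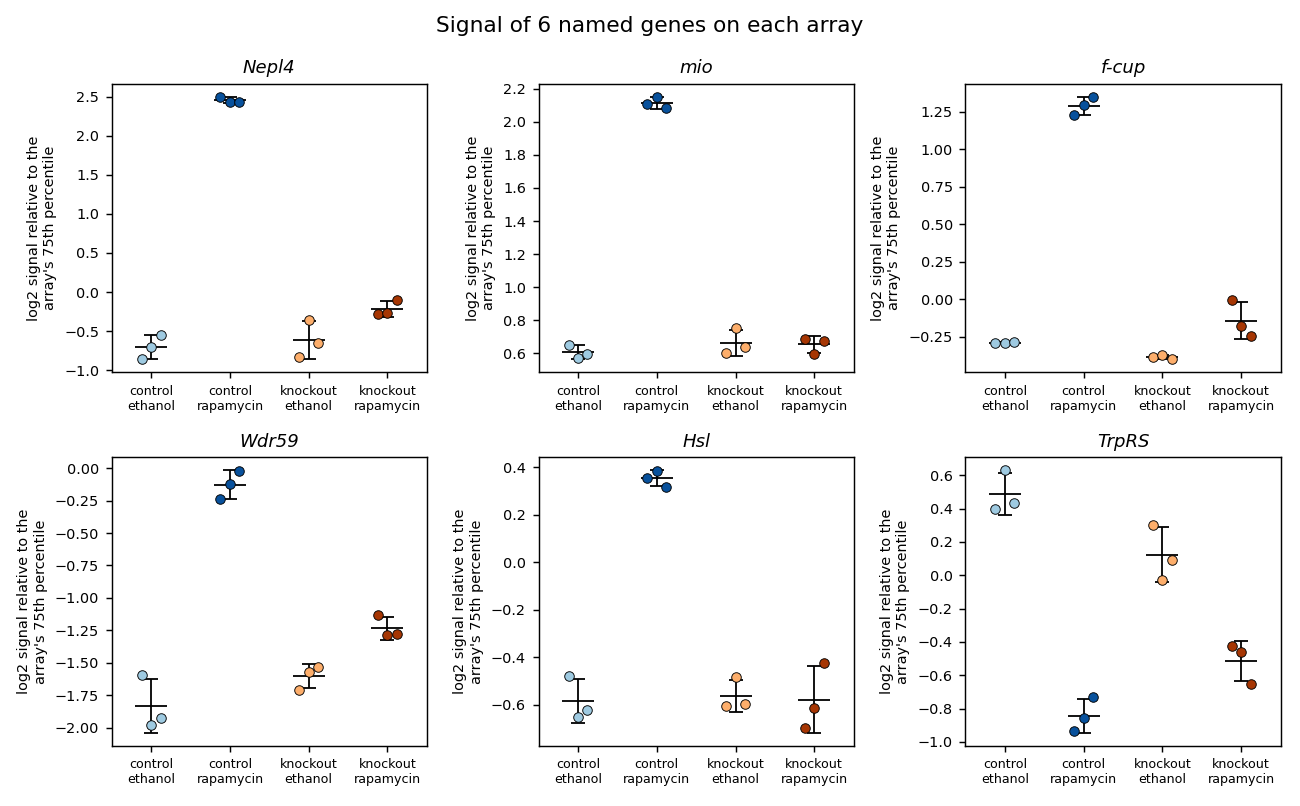
Log2 signal relative to the array's 75th percentile for 6 named genes. Points are single arrays, and horizontal lines with bars are the mean and SD of 3 arrays. Nepl4, mio, f-cup, Wdr59 and Hsl are higher on all 3 control rapamycin arrays than on any other array, and TrpRS is lower on both rapamycin groups than on the ethanol group of the same genotype.

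The second comparison gave the rapamycin response of knockout larvae. The snoRNA host genes Uhg5 (-1.23 ± 0.13, adjusted p = 0.000605), Uhg3 (-0.87 ± 0.15) and Uhg2 (-0.83 ± 0.12) fell, as did shop (-0.75 ± 0.16) and Rrp42, which encodes a subunit of the RNA exosome (-0.74 ± 0.12). RpL30 rose by 0.86 ± 0.16 (adjusted p = 0.00786), atos by 0.50 ± 0.11, Mob2 by 0.41 ± 0.09 and Wdr59 by 0.37 ± 0.11 (adjusted p = 0.0461). The call for Wdr59 held in 7 of 31 alternatives, with 0.03 under median centring, that for atos in 16 of 31, with 0.06 in the deposited value table, and that for Mob2 in 21 of 31, with 0.07 under median centring. The transcription factor gene cnc rose by 0.35 ± 0.09 (adjusted p = 0.0251), but its sign turned to -0.08 with quantile normalisation and in the deposited value table. Each value rests on 3 arrays per group. Of targets without a symbol, the probe used for FBtr0087087 was at least 62.5-fold higher in the group mean (adjusted p = 0.0448), a call that held in 9 of 30 alternatives. Its level over the knockout rapamycin arrays was -1.2 ± 3.5 (SD), so single arrays need not reach that bound. The other probes of FBtr0087087 had fitted rises of 3.26 and 3.14 on the log2 scale. They were well above background on only 4 and 3 of the 12 arrays. FBtr0082482 was at least 21.3-fold lower (adjusted p = 0.000436).

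In the lists, mRpL52 (-0.57 ± 0.14) and mRpL14 (-0.56 ± 0.16) fell in knockout larvae and mRpS16 (-0.41 ± 0.16, adjusted p = 0.102) did not pass. RpS7 fell by 0.64 ± 0.11, TrpRS by 0.64 ± 0.11, Vha13 by 0.35 ± 0.09 and ATPCL by 0.66 ± 0.18. Atg10 rose by 0.26 ± 0.06 (adjusted p = 0.0165), with -0.09 under median centring. The values of mio (-0.01 ± 0.06), Hsl (-0.02 ± 0.08), CtsB (-0.04 ± 0.14), Cpr49Ag (0.09 ± 0.13) and Cpr60D (0.03 ± 0.10) did not pass, nor did Ald1 (-0.34 ± 0.12, adjusted p = 0.087). Adjusted over the list alone, mRpS16 and Ald1 passed as well and the other lists gave the same counts. The cytosolic ribosomal protein set did not pass (camera adjusted p = 0.864).

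In knockout larvae 2876 targets passed, 1194 higher and 1682 lower, 292 of them at least 2-fold, and in 2860 the arrays of both groups did not overlap (34.5% of all tested targets against 10% by chance). Of the 1194 higher calls 823 were also higher in control larvae, where 254 would be shared by independent lists, and of the 1682 lower calls 1312 were also lower, against 367. Another 62 and 33 went the opposite way in control larvae. These 2 comparisons share no array in their groups, but a single model gave both the same spread per target. Both rapamycin groups also hold arrays with a raised roX2 signal. The lists are therefore not independent, and the counts for independent lists serve only as a reference. With slide as a block 263 targets passed, 248 of them among the 2876. Within slide 3, which holds a single knockout ethanol array, limma called 0 targets, with 2527 at an unadjusted p under 0.05, on a spread taken from the rapamycin arrays alone. Median centring gave a median of all targets of -0.33 in place of 0.01 and left 1437 calls, 6.54% of them higher against 41.5%, and the shares were 31.6% with quantile normalisation and 30.6% in the deposited value table, where the medians were -0.11. Without knockout rapamycin array 3 the balance turned, with 1879 higher and 1584 lower (54.3% higher). The count was 1323 without knockout ethanol array 1, 1870 without knockout ethanol array 3, 1855 without knockout rapamycin array 1 and 1547 without knockout rapamycin array 2.

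Arrays of the rapamycin groups differed in roX2, an RNA of the male dosage compensation complex, although all arrays are labelled female. Its level was -1.29 on control rapamycin array 3, 0.01 on knockout rapamycin array 1 and -1.10 on knockout rapamycin array 2. It was -5.83 on knockout rapamycin array 3 and between -9.06 and -6.90, not well above background, on the other 8 arrays. Tested targets named by clones of an adult testis cDNA library had a median level of -2.85, -2.004 and -3.22 on the first 3 of these arrays, and between -5.17 and -4.79 on all others. Without these 3 arrays, an alternative chosen after the data were seen, 186 targets passed in knockout larvae, where 1 rapamycin array then remains and is assumed to vary like the other groups, and 7097 passed in control larvae. The fitted rise of FBtr0087087 in knockout larvae was then 4.26 on the log2 scale, against 7.99 with all arrays. With the roX2 signal as a covariate it was 3.25 (adjusted p = 0.254). These values do not size the rise, because the target was not well above background on any knockout ethanol array.

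**Figure D2:**
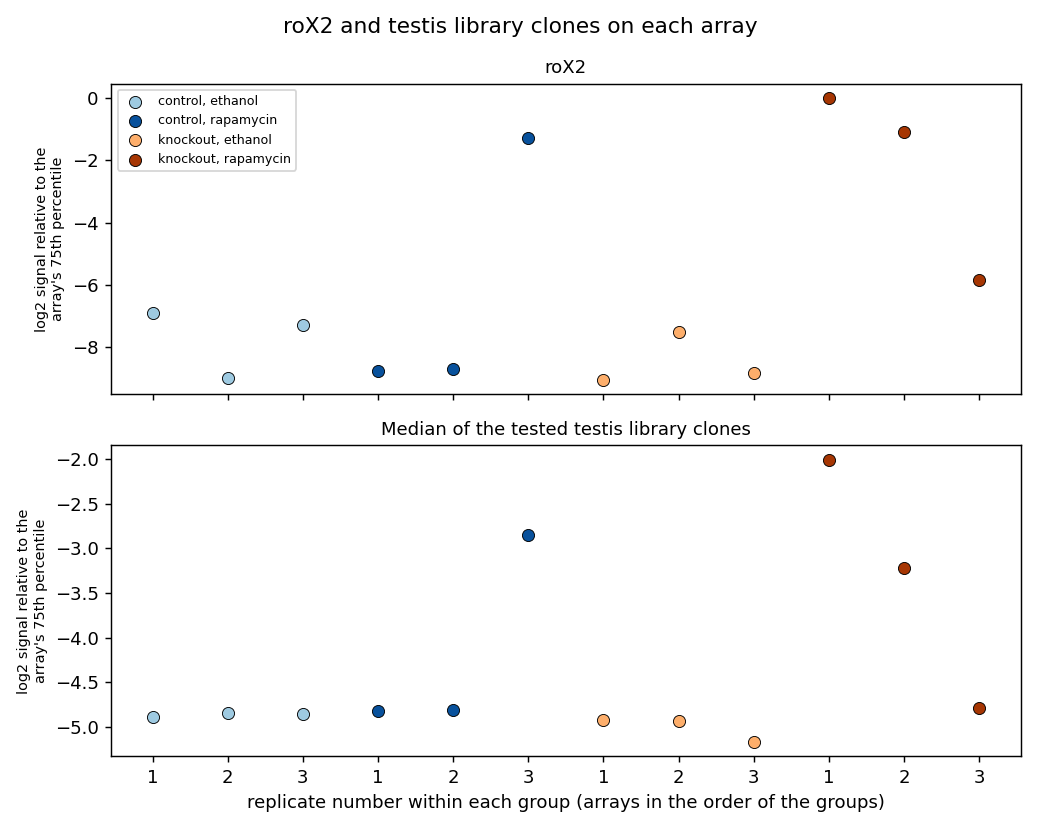
Log2 signal relative to the array's 75th percentile of roX2 (top) and the median over the 67 tested testis library clones (bottom) on each of the 12 arrays, in the order of the groups. Control rapamycin array 3 and knockout rapamycin arrays 1 and 2 are above all others in both panels.

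The third comparison asked whether the rapamycin effect differed between genotypes, as the effect in knockout minus that in control larvae. The rise of Nepl4 was smaller in the knockout, 0.40 ± 0.12 (log2, SE) against 3.16 ± 0.12 in control larvae (difference -2.76 ± 0.17, n = 3 arrays per group, adjusted p = 2.47e-05). The GATOR2 genes mio (difference -1.52 ± 0.08, adjusted p = 1.24e-05) and Wdr59 (-1.34 ± 0.15, adjusted p = 0.000538), f-cup (-1.34 ± 0.10, adjusted p = 5.61e-05) and Hsl (-0.95 ± 0.12, adjusted p = 0.000701) showed the same pattern. The fall of TrpRS was smaller in the knockout (difference 0.69 ± 0.15, adjusted p = 0.0142), and the cuticle gene Cpr49Ag, which fell in control larvae, had a difference of 1.05 ± 0.19 (adjusted p = 0.00576).

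Other named genes with a lower rapamycin effect in the knockout were snRNA:U11 (-1.29 ± 0.38), atos (-0.89 ± 0.16), lncRNA:alphagamma-element:CR32865 (-0.88 ± 0.18), kek1, encoding an inhibitor of the EGF receptor (-0.83 ± 0.20), and mxt (-0.78 ± 0.11). Those with a higher effect were aralar1 (0.73 ± 0.20), Cpr60D (0.51 ± 0.14), CrebA, a transcription factor gene of secretory cells (0.50 ± 0.10), Chpf (0.50 ± 0.13), Mob2 (0.47 ± 0.13), the laminin gene LanA (0.46 ± 0.12), cl (0.35 ± 0.10) and FeCH, encoding ferrochelatase (0.31 ± 0.09). For Mob2 the effect was -0.05 ± 0.09 in control and 0.41 ± 0.09 in knockout larvae. Of 29 alternatives, the call held in 8 for aralar1, 9 for cl and for FeCH, 10 for Cpr60D and for LanA, and 12 for Chpf and for Mob2. Values went down to 0.10 for cl and 0.18 for FeCH. The call for snRNA:U11 held in 10 of 28. CrebA rests on 1 of 2 probes, and the mean of both turned its difference to -0.25. With normexp and all spots kept, the difference was -0.03 for atos (adjusted p = 0.978), and turned to 0.43 for snRNA:U11, 0.09 for mxt and 0.21 for lncRNA:alphagamma-element:CR32865. Among targets without a symbol the effect on FBtr0087746 was 6.73 ± 1.14 in control and -1.28 ± 1.14 in knockout larvae, and that on FBtr0082176 was 4.22 ± 0.35 and 0.25 ± 0.35. FBtr0082176 was already high in knockout larvae on ethanol, at 3.66 ± 0.27 against 0.50 ± 0.82 (SD) in control larvae. On rapamycin its levels were 3.92 in knockout and 4.7 in control larvae. TC229084 was well above background only in control larvae on ethanol, and FBtr0074400 there and in knockout larvae on rapamycin, so their differences are not sized here. RpL30 did not pass (-0.01 ± 0.22), nor did the cytosolic ribosomal protein set (camera adjusted p = 0.859). The 3 mitochondrial ribosomal protein genes did not pass either, with 0.28 ± 0.20 for mRpL52, 0.46 ± 0.22 for mRpS16 and 0.28 ± 0.22 for mRpL14, nor did Atg10 (-0.24 ± 0.08, adjusted p = 0.073), Vha13 (0.29 ± 0.13), CtsB (-0.54 ± 0.20), Ald1 (0.49 ± 0.17) and ATPCL (-0.78 ± 0.26). These last 5 passed when adjusted over the list alone, and the other lists gave the same counts.

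Over the 4465 targets higher in the mean rapamycin effect, the median rise was 0.52 in control and 0.26 in knockout larvae. The median difference was -0.21, and 3314 (74.2%) rose less in the knockout. Adjusted over the list alone, 1348 passed as rising less and 54 as rising more. Over the 4144 targets lower in the mean effect the medians were -0.56 and -0.29 and the median difference 0.26, 3399 (82.0%) fell less in the knockout, and 1242 passed as falling less against 62 as falling more. The score of the rising targets was -1.05 ± 0.06 (SD, n = 3) on rapamycin against -1.68 ± 0.03 on ethanol in control larvae, and -1.25 ± 0.14 against -1.62 ± 0.02 in knockout larvae, a difference of effects of -0.26 (exact permutation p = 0.005, the smallest possible). For the score of the falling targets the difference of effects was 0.29 (exact permutation p = 0.01). Both permutations kept the targets selected with the real labels, so their p-values do not cover that selection. The result for the rising targets depended on knockout rapamycin array 3 and on the scaling. Without that array the difference of the score was 0.01 over targets selected again and -0.19 over the same targets, and the median difference was -0.12 and -0.20. Under median centring, with targets selected again, the difference of the score was 0.03. There 291 of 882 rising targets passed as rising less and 4 as rising more, and 60 of 5391 falling targets as falling less and 6 as falling more.

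Target by target, 2742 differences passed, 1244 with a higher and 1498 with a lower effect in the knockout, 788 of them at least 2-fold. With slide as a block 617 passed, 568 of them among the 2742. In that fit Nepl4 (-2.77), mio (-1.48), f-cup (-1.26), Wdr59 (-1.30), Hsl (-0.92), mxt (-0.85) and lncRNA:alphagamma-element:CR32865 (-1.11) still passed, the median difference of the rising targets was -0.23 over the same targets, and the other genes with a symbol no longer passed. Of these Cpr49Ag (1.25), aralar1 (1.02), kek1 (-1.02), TrpRS (0.82) and atos (-0.93) had differences at least as large as without the block, and that of LanA (0.33) was smaller. Median centring gave a median of all differences of -0.11 in place of 0.01 and left 329 calls, 23.7% of them with a higher effect against 45.4%. Without the 3 arrays with raised roX2, 980 passed.

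**Figure D3:**
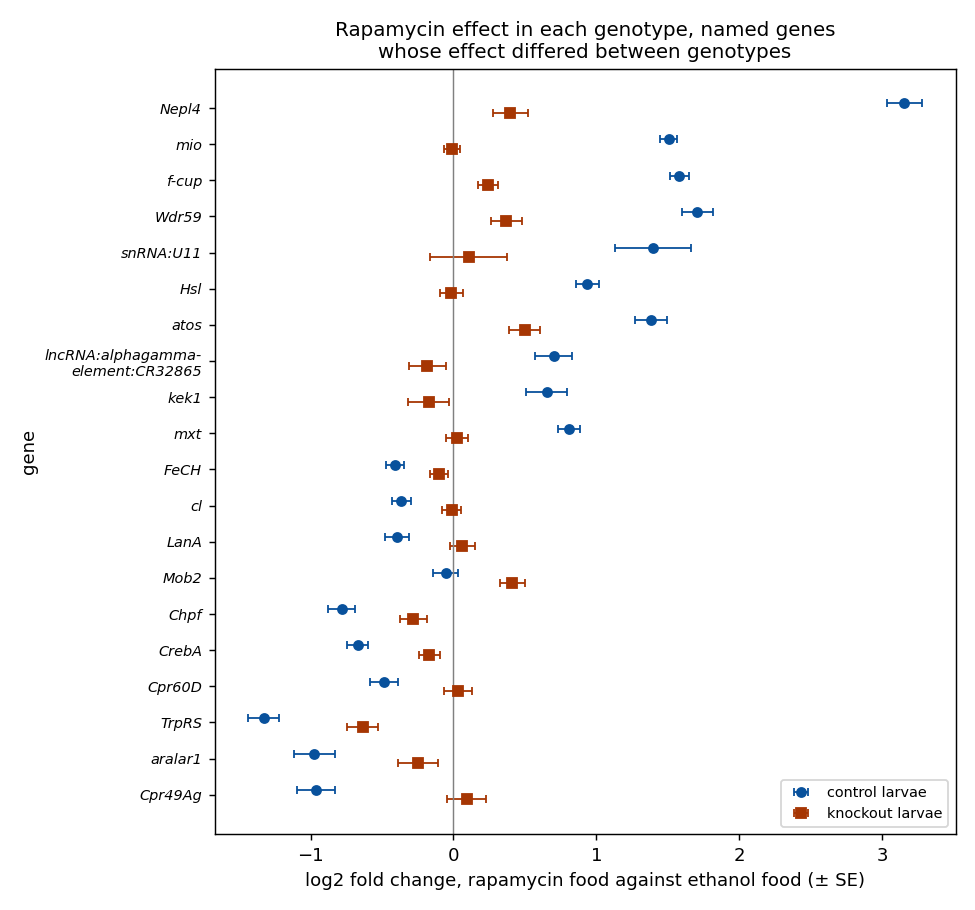
Log2 fold change of rapamycin against ethanol food (± SE, n = 3 arrays per group) in control and knockout larvae for the 20 named genes whose effect differed between genotypes. The control values run from 3.16 for Nepl4 to -1.33 for TrpRS, and apart from Mob2 the knockout value of each gene is the smaller in size.

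The fourth comparison set knockout against control larvae on ethanol food, and includes any difference in genetic background. The adult cuticle protein gene Acp65Aa was higher in the knockout by 1.36 ± 0.32 (log2, SE, n = 3, adjusted p = 0.0416), the minor spliceosome RNA snRNA:U12 by 0.72 ± 0.11 and kek1 by 0.72 ± 0.14. The value of snRNA:U12 turned to -0.20 with normexp and all spots kept. Lower in the knockout were lncRNA:cherub (-0.69 ± 0.14), Uhg2 (-0.52 ± 0.12), the flap endonuclease gene Fen1 (-0.51 ± 0.12), FeCH (-0.32 ± 0.06) and cl (-0.29 ± 0.07), with adjusted p from 0.0124 for snRNA:U12 to 0.0416. Of the genes that rose with rapamycin in control larvae, mio (0.06 ± 0.06) and Hsl (0.02 ± 0.08) did not pass, nor did snRNA:U11 (0.92 ± 0.27, adjusted p = 0.069), whereas kek1, which rose by 0.65 ± 0.14 there, was among the genes higher in the knockout. U84756 was higher by 7.33 ± 0.86 and TC228528 by at least 26.0-fold, and TC250150 was at least 171-fold and FBtr0084674 at least 60.3-fold lower (adjusted p = 1.43e-08). U84756 also varied within control larvae, at 0.69 ± 0.44 (SD) on ethanol and 4.6 ± 2.3 on rapamycin. With slide as a block neither U84756 (5.23, adjusted p = 0.542) nor TC228528 (adjusted p = 0.646) passed.

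On ethanol food 1200 targets passed, 546 higher and 654 lower, 251 of them at least 2-fold, and in 1199 the arrays did not overlap (30.4% of all tested targets against 10% by chance). The cytosolic ribosomal protein set did not pass (camera adjusted p = 0.277). Of list members only Acp65Aa passed. Adjusted over the list alone, mRpL52 and mRpL14 (-0.35 ± 0.14 and -0.41 ± 0.16) and TrpRS (-0.36 ± 0.11) passed as lower too. With slide as a block, 10 targets passed, 5 of them among the 1200 and including TC250150 and FBtr0084674 but none of the genes with a symbol, of which Acp65Aa (1.37), lncRNA:cherub (-0.66), Fen1 (-0.63) and cl (-0.42) kept their size, and the ribosomal protein set then passed as lower (camera adjusted p = 0.0344). No slide holds both groups. Without control ethanol array 3 only 55 targets passed as higher and 52 as lower. The count was 135 without control ethanol array 2, 2580 without control ethanol array 1, 169 without knockout ethanol array 3 and 419 without knockout ethanol array 2. It was 712, 656 and 710 without control rapamycin array 1, 2 or 3, and 711 without knockout rapamycin array 2, arrays that enter only through the common spread.

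The fifth comparison set knockout against control larvae on rapamycin food. Lower in the knockout were Nepl4 (-2.67 ± 0.12, log2, SE, n = 3, adjusted p = 7.69e-07), mio (-1.46 ± 0.06), f-cup (-1.43 ± 0.07), lncRNA:alphagamma-element:CR32865 (-1.23 ± 0.13) and Wdr59 (-1.11 ± 0.11, adjusted p = 6.96e-05). Higher in the knockout were Acp65Aa (1.71 ± 0.32), the fatty acid transport gene Fatp3 (1.20 ± 0.19), the lysozyme gene LysE (0.99 ± 0.25), Cpr49Ag (0.93 ± 0.13) and verm, encoding a chitin-binding deacetylase (0.69 ± 0.17). All 3 measured cuticle genes were higher, with Cpr60D at 0.60 ± 0.10 (adjusted p = 0.00156). Hsl (-0.93 ± 0.08), ATPCL, encoding ATP citrate lyase (-0.95 ± 0.18, adjusted p = 0.00399), CtsB (-0.48 ± 0.14) and Atg10 (-0.25 ± 0.06) were lower, and Ald1 (0.39 ± 0.12) and TrpRS (0.33 ± 0.11) higher. In the group means FBtr0087451 was at least 68.0-fold higher and FBtr0084674 at least 97.3-fold lower. The level of FBtr0087451 was -0.86 ± 2.58 (SD) over the knockout rapamycin arrays, so single arrays need not reach its bound.

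On rapamycin food 5225 targets passed, 2420 higher and 2805 lower, 1036 of them at least 2-fold, and in 5179 the arrays did not overlap (44.9% of all tested targets against 10% by chance). The ribosomal protein set did not pass (camera adjusted p = 0.484), and adjusted over the list alone every list gave the same counts. Of 571 targets that passed on both foods 489 kept their direction, where 168 would be shared in direction by independent lists. Both lists rest on the model's common spread, so they are not independent. With slide as a block 788 passed, 759 of them among the 5225. All 5 named genes that were lower still passed, whereas the 3 cuticle genes, Fatp3, LysE and verm did not. The change fell to 0.09 for LysE, but was 1.08 for Cpr49Ag, 1.41 for Acp65Aa, 1.09 for Fatp3 and 0.92 for verm. FBtr0087451 did not pass either (adjusted p = 0.833), and its call held in 17 of 29 alternatives. Its fitted change was 2.48 on the log2 scale, against 7.86 without the block. Neither sizes the change, because the target was not well above background on any control rapamycin array. No slide holds both groups. Median centring gave a median of all targets of -0.13 in place of 0.01 and left 1666 calls, 23.1% of them higher against 46.3%, and without the 3 arrays with raised roX2 2420 targets passed.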

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

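All tests of the 3 arrays with raised roX2 were chosen after their levels were seen. Of the tests of the smaller response in the knockout, that with slide as a block was written beforehand. Leaving out the 3 arrays and using roX2 as a covariate were chosen after the data were seen. Reading these tests over the same targets was chosen after the alternatives were seen.

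The rapamycin effect differed between genotypes for 2742 targets. The median difference was -0.211 over targets that rose in the mean effect and 0.261 over those that fell. Among 100 arrangements of the genotype labels within food, the labels' own and a random part of the rest, 3 gave at least 2742 targets. That share, under 0.05, argues against a chance arrangement in which genotype has no effect on either food. It does not test the difference of effects alone, because the exchange breaks the genotype effect on each food. The highest other count, 5324, came from exchanging the genotype labels of all rapamycin arrays, which tests the sum of both genotype effects. That sum cannot be told apart from a slide or scan effect, because no slide holds both genotypes on the same food. Another arrangement, which exchanged control ethanol arrays 2 and 3 with knockout ethanol arrays 1 and 3, gave 3386.

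Technical sources were weighed for the smaller rise in the knockout. Without the 3 arrays with raised roX2 the median difference was -0.264 over the same targets, but a single knockout rapamycin array then remains, array 3, whose rising score was the lowest (-1.39 against -1.11 and -1.23), so this decides nothing. With all arrays and roX2 as a covariate it was -0.242 over the same targets and -0.253 over targets selected again. Both lie beyond 0.0797, the pooled SD of the array scores, which is not the error of a median difference. That fit assumes 1 slope for all groups, and array 3 is the only knockout rapamycin array outside the 3. It argues only against a linear trend with roX2 as the whole cause, and does not decide the dependence on array 3. With slide as a fixed block the median difference was -0.229 over the same targets and -0.357 over targets selected again. In that fit the control effect rests on a single rapamycin array, on slide 1. The knockout effect rests on a single ethanol array, on slide 3. No slide holds both genotypes on the same food, so a slide or scan effect is left undecided. Loss of REPTOR is the biological explanation the design offers, and it may account for the pattern. Genetic background was untested, and slide or scan is undecided. The rising score is left open by a difference of 0.01 without knockout rapamycin array 3.

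The genes behind this difference include Nepl4 (-2.758), mio (-1.517), f-cup (-1.338), Wdr59 (-1.336), snRNA:U11 (-1.293), Hsl (-0.953), atos (-0.885), lncRNA:alphagamma-element:CR32865 (-0.884), kek1 (-0.826) and mxt (-0.783), whose rapamycin effect was lower in the knockout. It was higher for Cpr49Ag (1.054), aralar1 (0.725), TrpRS (0.693), Cpr60D (0.514), CrebA (0.503), Chpf (0.502), Mob2 (0.465), LanA (0.459), cl (0.353) and FeCH (0.308). Of targets without a symbol FBtr0087746 had -8.007 and FBtr0082176 -3.970. On ethanol FBtr0082176 was already higher in knockout than in control larvae, 3.66 against 0.50. TC229084 had a fitted 3.868 and FBtr0074400 a fitted 3.659, which size nothing because both were not well above background in at least 2 groups.

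Control rapamycin array 3 and knockout rapamycin arrays 1 and 2 stood apart on the first principal component (52.4% of the variance), at 89.6, 121 and 70.7 against -44.1 to -0.414 for the others, and had a raised roX2 signal although labelled female. Well above background on these 3 arrays and on knockout rapamycin array 3, roX2 was so on none of the ethanol arrays. All 3 knockout rapamycin arrays were thus raised. Its signal stood above the ethanol arrays of the same genotype by 6.42, 8.47 and 7.37. On knockout rapamycin array 3 it stood above them by 2.63 (percentile 99.6 of 500 targets of near signal). These differences start from background and so do not size the rise. The level of roX1, another male dosage compensation RNA, was 3.35, 3.88 and 2.91 on the 3 arrays and between -1.57 and 0.43 on the other 9.

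Brighter labelling would lift targets of equal signal alike, but the testis library clones shifted by more than 100% of 10000 random sets matched on signal on each of the 3 arrays, which argues against it. A slide or scan effect is argued against by the 5 other arrays of slides 2 and 3, all 5 of which had roX2 more than 2 log2 units lower, though knockout rapamycin array 3 was among the 5. A response shared by all rapamycin arrays is argued against by 2 of the 6, both of control larvae, with roX2 within the ethanol range, which leaves a response of single arrays or of the knockout open. Male larvae or tissue in these samples may be the source: the 127 testis library clones shifted by 1.07, 1.59 and 0.532 on the 3 arrays, above the 95th percentile of the matched sets (0.28, 0.09 and 0.16), and by 0.00, 0.14 and -0.03 on the other rapamycin arrays. Of these clones 67 were well above background on all arrays of at least 1 group, which may be the knockout rapamycin group. That count does not show whether they are specific to testis. The median of these 67 on the ethanol arrays was between -5.17 and -4.84. The lowest signal well above background on those arrays was -7.21 to -6.89.

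For the other counts, 10 splits of 6 arrays are too few for a share under 0.05. The labels gave 8082 targets for rapamycin in control larvae (1 of 10 splits, highest other 0), 2876 for rapamycin in knockout larvae (1 of 10, highest other 0), 1200 for knockout against control on ethanol (1 of 10, highest other 0) and 5225 on rapamycin (1 of 10, highest other 861). The split with 861 exchanged control rapamycin array 3 with knockout rapamycin array 3 and so sets the 3 arrays with raised roX2 against the others. For the mean rapamycin effect 1 of 100 arrangements gave as many as the 8609 of the labels, with 5555 as the highest other. These too were a random part of those possible, and the share, under 0.05, argues against a chance arrangement there.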

How the results depend on the processing

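The alternatives without the 3 arrays with raised roX2, with roX2 as a covariate and with both forms of normexp, the added sets, and the reading of the score under alternatives, were chosen after the data were seen. Of 2551 values of the named genes under alternatives, 1991 kept their direction and side of the threshold, 551 kept only the direction and 9 reversed. The differences between genotypes of Nepl4, mio and f-cup passed under all 29 alternatives run, with adjusted p up to 0.0166, and that of Wdr59 under 28 of 29. Signal over background limits the targets near the floor, whose changes are bounds. Unless stated, the cause of a change was not tested.

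With quantile normalisation 295 targets passed for knockout against control on ethanol and the falling targets' median difference was 0.175. In the deposited value table these were 381 and 0.152. The effect of rapamycin on cnc in knockout larvae reversed to -0.075 and -0.080. Median centring left 3848 targets for rapamycin in control larvae, 1437 for rapamycin in knockout larvae, 329 for the difference, 119 and 1666 for the knockout on ethanol and rapamycin, and median differences of -0.327 and 0.115, with a difference of the rising score of 0.028. Among calls of the mean effect it left 14.1% higher, and quantile normalisation 40.5% and the deposited values 39.3%, against 51.9%. Without the filter on dim probes 1917 targets passed for rapamycin in knockout larvae and 554 for the knockout on ethanol. With the mean of all probes the difference for CrebA reversed to -0.250, since its dimmer probe went the other way.

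Slide as a fixed block, with fewer residual degrees of freedom, left 4683 and 263 targets for rapamycin in control and knockout larvae, 617 for the difference, 10 and 788 for the knockout on ethanol and rapamycin, and 4856 for the mean effect. The rising targets' median difference was -0.357, and 1 gene list passed. Slide as a random block (correlation -0.161) gave 4391 targets for rapamycin in knockout larvae, 4994 for the difference and 4105 for the knockout on ethanol. Array weights gave 4178 for the difference and 4493 for the knockout on ethanol. Using only the groups compared gave 509 for rapamycin in knockout larvae and 158 for the knockout on ethanol. Within slide 1, where 1 rapamycin array adds no spread of its own, 2799 passed for rapamycin in control larvae. Within slide 3, limma called 0 for rapamycin in knockout larvae (2527 at an unadjusted p under 0.05).

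Requiring a 2-fold change left 1590 and 292 for rapamycin in control and knockout larvae, 788 for the difference, 251 and 1036 for the knockout on ethanol and rapamycin, and 883 for the mean effect. An adjusted p under 0.01 left 919 for rapamycin in knockout larvae, 1162 for the difference, 96 and 3008 for the knockout on ethanol and rapamycin, and 5693 for the mean effect.

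Normexp with all spots kept left 3378 and 476 for rapamycin in control and knockout larvae, 560 for the difference, 43 and 1670 for the knockout on ethanol and rapamycin, 3317 for the mean effect, and a rising targets' median difference of -0.444. Over the targets of the main comparison that median was 0.058, where the median of all differences was 0.32. The rise of atos in control larvae was then 0.335 and its difference -0.026. It reversed snRNA:U11 (-0.442 for rapamycin in control larvae and 0.429 for the difference), mxt (-0.053 and 0.085), the difference for lncRNA:alphagamma-element:CR32865 (0.213) and the knockout effect on ethanol for snRNA:U12 (-0.196). Without 4 spots of high local background on 1 array, the same correction reversed 0 of 85 named results. Normexp on mean signals was not run.

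Without the 3 arrays with raised roX2, 186 passed for rapamycin in knockout larvae, where 1 rapamycin array is left, 980 for the difference, 450 and 2420 for the knockout on ethanol and rapamycin, and the rising targets' median difference was -0.324. With roX2 as a covariate 1404 passed for rapamycin in knockout larvae.

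Leaving out single arrays gave 6562 to 8291 targets for rapamycin in control larvae, 1323 to 3463 for rapamycin in knockout larvae, 1858 to 2966 for the difference, 3893 to 5534 for the knockout on rapamycin, and 7445 to 8888 for the mean effect. For the knockout on ethanol the highest count was 2580, and the lowest, about 1.1e+02, had 55 higher and 52 lower, without control ethanol array 3. The median differences were -0.280 to -0.119 and 0.208 to 0.307, with -0.119 without knockout rapamycin array 3 (-0.197 over the same targets), where the difference of the rising score was 0.011 (-0.185 over the same targets), and 0 gene lists passed throughout.

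Replicate numbers did not pair the arrays: 2 of 18 same-numbered pairs correlated above 0.1 in their deviations (range -0.818 to 0.178), and 0 of 12 arrays correlated best with their own number. With the replicate block 7305 and 1770 passed for rapamycin in control and knockout larvae, 1962 for the difference, 279 and 4432 for the knockout on ethanol and rapamycin, and 7594 for the mean effect.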

Other observations

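The sets described here were chosen after the data were seen, and their tests are not independent of that choice.

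Of 15 small structural RNAs and snoRNA host genes measured, 0 rose and 6 fell in knockout larvae on rapamycin, with a median of -0.175 over all 15. Those that fell were Uhg5 (-1.23), Uhg3 (-0.87), Uhg2 (-0.83), snRNA:U12 (-0.59), RNaseMRP:RNA (-0.57) and 7SLRNA:CR32864, the RNA of the signal recognition particle (-0.54). The other 9 did not pass. The set passed with the preset correlation (adjusted p = 0.00811) but had adjusted p = 0.406 with an estimated correlation. In control larvae 2 rose and 6 fell, among them Uhg5 (-1.83), Uhg2 (-1.07), Uhg3 (-0.77) and 7SLRNA:CR32864 (-0.40), and the set did not pass (adjusted p = 0.418).

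Long noncoding RNAs (52 measured, 7 higher and 1 lower, adjusted p = 0.00811) and antisense RNAs (35 measured, 4 higher and 1 lower, adjusted p = 0.0357) shifted up in knockout larvae on rapamycin, as did the testis library clones (67 measured, 5 higher and 4 lower, adjusted p = 0.00811). With an estimated correlation none of these passed (adjusted p = 0.406, 0.406 and 0.67), and 0 sets passed with the roX2 signal as a covariate. Both knockout rapamycin arrays 1 and 2 had the raised roX2 signal. Among the long noncoding RNAs, lncRNA:CR43301 rose by 1.33 and lncRNA:CR9162 fell by 1.14, and among the antisense RNAs asRNA:CR44029 rose by 1.93 and asRNA:CR43767 fell by 0.69. Clones of larval (adjusted p = 0.0506), head (0.125), embryo (0.801), cell line (0.847) and ovary (0.904) libraries did not pass in knockout larvae.

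In the other comparisons no added set passed. The lowest adjusted p was 0.116 for long noncoding RNAs with rapamycin in control larvae, 0.263 for antisense RNAs in the difference, 0.118 for cell line clones on ethanol food and 0.226 for head and embryo clones on rapamycin food. The male dosage compensation RNAs roX1 and roX2 are too few for a set test. The rapamycin effect on roX1 did not pass in control larvae (1.68 ± 1.08) or in knockout larvae (3.58 ± 1.08, adjusted p = 0.0526). That on roX2 did not pass either (adjusted p = 0.593 in control and 0.0696 in knockout larvae). As roX2 was at background on the ethanol arrays, its rise in knockout larvae is bounded only in the group mean, at 29.3-fold or more. Levels of 0.01, -1.10 and -5.83 on the 3 knockout rapamycin arrays enter that mean, so single arrays need not reach it. In control larvae only 1 rapamycin array was well above background, so the effect on roX2 there is not sized.

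FBtr0084674 and TC250150 were well above background on all 6 control arrays and on 0 of the 6 knockout arrays. FBtr0084674 averaged -1.27 ± 0.11 and -0.65 ± 0.19 in control larvae on ethanol and rapamycin, and TC250150 0.24 ± 0.21 and -1.24 ± 0.17. Neither has a gene name here, so whether either lies in the deleted region was not analysed.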
